A study of Mus musculus with 33 samples.

How the data were processed

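RNA was measured by CEL-seq2 in 33 libraries of live CD45+CD8+ T cells sorted from mouse skin, in 16 sorted groups, 17 libraries in the first experiment and 16 in the second. The deposited tables hold counts, raw reads per gene and library. Per the submitters' processing notes, bcl2fastq 2.2, BWA 0.7.15 and HTSeq were used with the GRCm38 genome. Whether reads were collapsed by molecular barcode and how strands were used is not given in the sources used here, and the values are treated as reads. Genes were placed by symbol and chromosome on GENCODE vM21 (GRCm38), in which 18179 of 19448 gene rows were found. Rows of external control transcripts (ERCC), 0 to 16 reads per library, were left out.

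Library totals ran from 2442825 to 8515297 counts (10068 to 13176 genes detected) in the first experiment and from 2937814 to 13629838 (10514 to 12806 genes) in the second. Between libraries of the same group the correlation of log2 CPM was 0.887 to 0.950, and no library repeated another. The test on simulated data below was run for 2 comparisons, and none was run for 2 libraries against 2. Lower limits of folds cover counting error only.

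The count table headers hold codes for the groups, and a group was taken from a header only where the labels leave a single reading. That held for day 0 acetone, for the GFP state of every day 1 library, and for day 2 CD69+CD103+ cells. The other codes fix a library's set but not which treatment, day or subset it is, and no group was read from expression values or from the order of columns. Day 1 arms I and II, day 0 TA and day 6 sets K, L and M, day 2 subsets U, V and W, and day 11 and day 42 sets P, Q, R and S therefore carry neutral names. In the second experiment both replicates of a group share a code, and they are numbered 1 and 2 here without telling sample A from B.

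Of 22 comparisons fixed before the data were examined, those that need the arm named were made as differences between arms I and II, without saying which is TA: TA against acetone at day 1 in GFP-negative and in GFP-positive cells, GFP-positive against GFP-negative in each arm, and the difference between these. The mean of the GFP difference over both arms, day 1 against day 0 acetone over both arms, day 11 and day 42 together against day 2, and CD69+CD103+ against the mean of the other day 2 subsets were made in place of comparisons that need named groups. For TA at day 0 and day 6, TA or day among day 11 and day 42, and CD69, CD103 or their interaction at day 2, the 3 possible contrasts were run and their counts are given. The mean of the 4 TA effects, TA at day 11 and at day 42 apart, the day 6 changes and the differences in response between TA and acetone were not analysed here.

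Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the sorted group, libraries scaled by TMM, dispersions estimated robustly, and contrasts tested by the quasi-likelihood F test. Each fit held 1 mean per group and all libraries of an experiment. This left 11588 genes in the first and 12236 in the second experiment. p-values were adjusted by Benjamini-Hochberg over all genes of a comparison and a gene was called under 0.05, and the SE of a log2 fold change is its size over the square root of F. Where a group had no count, the lower limit of the fold takes 3 counts over that group. Of 27 gene lists fixed before the data were examined, 26 had 5 or more tested genes and were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Members were also adjusted over their list alone.

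Genes to be named were set by a rule fixed before the data were examined. It takes Itgae, Cd69, Nr4a1, Tsc22d3, Fkbp5 and Per1. It takes the 10 called genes with the largest log2 fold change in each direction, at 10 CPM or more in the higher group, without predicted genes, pseudogenes and receptor segments. Their libraries must not overlap between the groups compared, or, for a mean over strata, the change must have the same sign in every stratum. It also takes up to 4 members, by smallest p, of each list called. From these the text names mainly genes that kept their call under all alternatives. Nr4a1 describes the GFP sort at day 1, and Itgae and Cd69 the sort of subsets at day 2.

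On simulated counts with 200 changed genes, edgeR recovered 46 of 100 genes changed 2-fold and 90 of 100 changed 4-fold in the GFP comparison over both arms (11009 genes), with 9 of 145 calls false (6.21%), and DESeq2 recovered 47 and 91 with 24 of 162 false (14.8%). For day 11 and day 42 against day 2 (11683 genes) edgeR recovered 25 and 83 of 100, with 7 of 115 calls false (6.09%), and DESeq2 35 and 85 with 42 of 162 false (25.9%). No recovered gene had the wrong sign.

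Alternatives fixed before the data were examined were size factors by median of ratios, no low-count filter, the Wald test of DESeq2 1.42.0, a replicate block (first experiment only), leaving out each library in turn, and an estimated correlation in the list tests. Alternatives chosen after seeing the data were libraries thinned to equal totals (2442825 and 2937814 counts), mitochondrial transcripts left out, and keratinocyte genes left out. The GFP comparison, day 1 against day 0, and the contrasts of 2 against 2 sets were also refitted over all 35 splits of their libraries. Rules for outlying samples need groups of 4 or more and were not applied, since groups hold 2 or 3 libraries. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.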

Results

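RNA of CD8 T cells sorted from mouse skin was sequenced in 33 libraries. The mice were allergic to the hapten dinitrofluorobenzene (DNFB), a model of allergic contact dermatitis in which CD8 T cells mediate the inflammation. The series asked how a topical glucocorticosteroid (TA, 0.01%) acts on resident memory T cells (TRM), CD8 T cells that stay in the skin and carry CD69 and CD103. The first experiment held 17 libraries of CD69+CD103+ TRM from Nur77GFP mice. In these mice GFP reports recent signalling through the T cell receptor (TCR). They covered day 0, just before DNFB retest (GFP-negative; 3 acetone and 2 TA), day 1, 24 hours later (GFP-negative and GFP-positive, 2 libraries each for acetone and for TA), and day 6, 144 hours later (GFP-negative; 2 acetone and 2 TA). The second experiment held 16 libraries from C57BL/6 mice, 2 per group. They covered 4 untreated subsets by CD69 and CD103 at day 2 after challenge. They also covered CD69+CD103+ TRM at day 11 and day 42 after DNFB, with acetone or TA as treatment.

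The day 1 libraries fall into 2 treatment arms, acetone and TA, each with its GFP-negative and GFP-positive cells. The column headers used here carry codes and not treatments, so the arms are called arm I and arm II, and which of them received TA was not used here. Arm I held 5440609 to 8515297 counts per library with 22.4 to 28.6% on mitochondrial transcripts, and arm II 2442825 to 3262545 with 29.3 to 36.7%. Replicates are lettered as separate samples, but nothing says that they came from separate animals, so the p-values measure only the spread between these samples. Values are CPM (counts scaled to library size) as mean ± SD over libraries, and log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

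The comparison of GFP-positive with GFP-negative TRM at day 1 asked which transcripts accompany recent TCR signalling. Averaged over both arms (4 libraries against 4), the chemokine genes Xcl1 (ENSMUSG00000026573.7; chromosome 1, 164931644 to 164935527, minus strand, GRCm38), Ccl1 and Ccl3 and the cytokine genes Il3 and Ifng were higher in GFP-positive cells. Xcl1 stood at 14629 ± 7846 CPM against 109 ± 40.8 (log2 6.97 ± 0.13, adjusted p = 2.58e-18) and was higher in both arms. Log2 differences were 5.60 ± 0.12 for Ccl1, 4.36 ± 0.12 for Ccl3, 6.27 ± 0.18 for Il3 and 2.72 ± 0.12 for Ifng, which encodes interferon gamma. Penk, which encodes proenkephalin, was higher by 6.84 ± 0.51, at 389 ± 231 CPM against 2.91 ± 0.757. Susd2, a membrane protein gene, was lower (log2 -4.13 ± 0.27), at 2.58 ± 1.20 CPM against 43.5 ± 13.2. Of 11588 genes tested, 1402 passed an adjusted p of 0.05, 648 higher and 754 lower in GFP-positive cells, and 376 and 524 of these by over 2-fold. With keratinocyte genes left out, a choice made after seeing the data, 741 were higher and 716 lower.

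By gene list, 27 of 35 TCR activation genes were higher (29 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.17e-38). They included the costimulatory receptor gene Tnfrsf9 (4-1BB; log2 2.84 ± 0.15). Of 25 effector genes, 15 were higher and 1 lower (17 and 1 adjusted over the list alone). In the dissociation and heat shock list 17 of 33 were higher (19 higher and 1 lower adjusted over the list alone), among them the stress gene Gadd45b at 2.30 ± 0.14 and the chaperone genes Hspa5 at 1.28 ± 0.13 and Hsp90ab1 at 0.86 ± 0.08. In the CD4 and Treg list 5 of 10 were higher (5 higher and 1 lower adjusted over the list alone). Among those that rose are genes also induced in activated CD8 cells: Areg, which encodes the growth factor amphiregulin (2.70), Nrp1 (4.31), Tnfrsf4 (OX40; 2.48) and Il2ra (CD25; 1.85). Of 35 interferon response genes 12 were lower (14 adjusted over the list alone), such as Ly6e at -0.97 and the GTPase gene Gbp4 at -1.73.

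In 3 further lists the camera call was lost with an estimated correlation. Of 21 inhibitory receptor genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone), with Cd160 at 4.80 ± 0.53, Havcr2 (TIM-3) at 1.12 ± 0.17 and the regulatory cytokine gene Il10 at 4.52 ± 0.36 (adjusted p = 0.0541 with an estimated correlation). Of 23 glycolysis genes 8 were higher and 4 lower (11 and 6 adjusted over the list alone; adjusted p = 0.0752 with an estimated correlation), the glucose transporter gene Slc2a3 rising by 1.88 ± 0.28 and the phosphoglycerate kinase gene Pgk1 by 0.83 ± 0.11. Of 39 proliferation genes 1 was higher and 9 were lower (4 and 14 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), with Stmn1, a microtubule regulator of dividing cells, at -1.16 and the tubulin gene Tubb5 at -0.91. Nr4a1, the gene behind the reporter, was higher by 1.83 ± 0.13, which describes the sort and is no finding. The reporter transcript eGFP, named after its values were seen, overlapped, at 5.55 to 20.1 CPM (median 10.9) in GFP-positive and 1.59 to 11.1 CPM (median 7.86) in GFP-negative libraries, and was not called in either arm (log2 2.08 ± 0.99 and -0.43 ± 0.99). Both GFP states were sorted as CD69+CD103+. Itgae, which encodes CD103, ranged from 31.7 to 58.0 CPM in GFP-positive and from 58.7 to 161 CPM in GFP-negative libraries. The glucocorticoid-induced gene Tsc22d3 was lower (-0.97 ± 0.16). Of other cells' markers, 5 of 23 mononuclear phagocyte genes were higher and 2 lower (camera adjusted p = 0.0591), and 5 of 31 keratinocyte genes were lower and 1 higher (0.0591). Mitochondrial transcripts took 22.4 and 25.9% of counts in GFP-positive against 28.6 and 28.4% in GFP-negative libraries of arm I, and 29.3 and 30.1% against 35.8 and 36.7% in arm II. Within the arms the same comparison called 621 genes in arm I and 935 in arm II. In arm I, the count was 312 and 412 without GFP-negative A and B, and 322 and 341 without GFP-positive A and B.

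The arms shared part of the GFP difference and differed in part of it. Il3 was higher in GFP-positive cells by log2 8.75 ± 0.28 in arm I and 3.79 ± 0.25 in arm II, a difference between the arms of -4.96 ± 0.33 (adjusted p = 7.26e-08). The GFP difference was also smaller in arm II for Ccl3 (-2.60 ± 0.22), Ifng (-1.44 ± 0.22), the T cell growth factor gene Il2 (-5.22 ± 0.77) and the inflammatory cytokine gene Tnf (-2.79 ± 0.42). Ptpn22, a phosphatase that restrains TCR signalling, was higher in GFP-positive cells of arm I (0.81 ± 0.15) and did not pass in arm II (-0.45 ± 0.15). The MHC class II gene H2-Ab1 (6.73 ± 0.47) and the basal keratin gene Krt14 (2.10 ± 0.23) were higher, and the epidermal keratin gene Krt2 (-4.46 ± 0.35) lower, in GFP-positive cells of arm II, and none of these 3 passed in arm I (0.13 ± 0.28, -0.60 ± 0.21 and -0.33 ± 0.28). Over both arms H2-Ab1 ranged from 87.8 to 206 CPM in GFP-positive and from 0 to 190 CPM in GFP-negative libraries. Krt14 ranged from 305 to 575 and from 64.3 to 842 CPM. Both were lower in arm II than in arm I in GFP-negative cells. Their larger GFP difference in arm II thus need not mean more transcript in its GFP-positive cells than in those of arm I. In all 103 genes differed between the arms in their GFP difference, 74 with a higher and 29 with a lower value in arm II. Without the low-count filter the count was 310, and it was 47 without arm I GFP-negative A, 47 without arm I GFP-positive A and 64 without arm I GFP-positive B. Among the 11588 genes, 156 were higher in GFP-positive cells of both arms, where independent lists would share 11.0, 154 were lower in both, against 14.1, and 8 moved in opposite directions, against 25.1. Over all these genes the log2 differences of the arms correlated by 0.142.

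Of the gene lists, 4 of 31 keratinocyte genes had a higher and 1 a lower GFP difference in arm II (11 and 1 adjusted over the list alone), a call lost at adjusted p = 0.112 with an estimated correlation. In the proliferation list 4 of 39 had a higher value (10 adjusted over the list alone; adjusted p = 0.0773 with an estimated correlation). In GFP-negative cells 17 of the 31 keratinocyte and 18 of the 39 proliferation genes were lower in arm II than in arm I. A higher value in these lists thus need not mean more transcript in GFP-positive cells of arm II. In the TCR activation list 5 had a lower and 1 a higher value (6 and 2 adjusted over the list alone; adjusted p = 0.0773 with an estimated correlation). The test and the median of that list were below 0 and its mean above 0. CD8 identity genes (3 of 17 higher), inhibitory receptors (1 of 21 lower), NK and innate lymphoid genes (0 of 12) and oxidative phosphorylation genes (0 of 49) were called by camera with the preset correlation only. With an estimated correlation they had adjusted p = 0.153, 0.0773, 0.0773 and 0.24. In arm I the lists of keratinocyte (4 of 31), proliferation (14 of 39) and interferon response genes (7 of 35) were lower in GFP-positive cells, and each call held with an estimated correlation. Inhibitory receptors (6 higher and 1 lower of 21; adjusted p = 0.00535 with an estimated correlation) and type 17 and type 2 genes (4 higher and 1 lower of 12; 0.0272) were higher in arm I, and inhibitory receptors were not called in arm II (camera adjusted p = 0.279). Type 17 and type 2 genes were not called in arm II either (4 higher and 2 lower; camera adjusted p = 0.265). Nor did that list differ between the arms in its GFP difference (camera adjusted p = 0.345). In arm II proliferation genes were not called (4 higher and 2 lower; camera adjusted p = 0.988), nor were keratinocyte genes (5 higher and 3 lower; 0.539). There 7 of 35 interferon response genes were lower too (camera adjusted p = 0.032; adjusted p = 0.0582 with an estimated correlation), and 7 of 23 glycolysis genes were higher (adjusted p = 0.0761 with an estimated correlation).

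The comparison between the arms asked what TA changes 24 hours after retest. With the treatment of each arm not used here, values are given as arm II against arm I. In GFP-negative TRM (2 libraries against 2) the granzyme gene Gzmb (ENSMUSG00000015437.5; chromosome 14, 56258838 to 56262260, minus strand, GRCm38), whose product kills target cells, was at 1589 ± 23.2 CPM in arm II and 23532 ± 3309 in arm I (log2 -3.89 ± 0.15, adjusted p = 2.36e-12). Lower in arm II were also Gzmc (-3.50 ± 0.32), Ifng (-1.80 ± 0.16), the granule protein gene Nkg7 (-1.26 ± 0.13), and Thy1 (-1.41 ± 0.11) and Cd44 (-1.17 ± 0.13), which encode surface proteins of T cells. Higher in arm II were Pik3ip1, an inhibitor of PI3 kinase (4.97 ± 0.59), the phosphatase gene Ptpn22 (1.79 ± 0.16) and Tsc22d3, a glucocorticoid-induced gene, at 272 ± 56.6 CPM against 105 ± 15.3 (1.37 ± 0.23). In all 775 genes differed, 230 higher and 545 lower in arm II, 177 and 432 by over 2-fold. The count was 356 without arm I GFP-negative A and 491 without arm I GFP-negative B.

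In these GFP-negative cells 18 of 39 proliferation genes were lower in arm II (24 lower and 1 higher adjusted over the list alone), Stmn1 at -3.08 ± 0.23 and the DNA topoisomerase gene Top2a at -5.34 ± 0.53. Of 35 interferon response genes 13 were lower (20 adjusted over the list alone), with the GTPase gene Gbp2 at -4.69 ± 0.34, Ly6a at -2.07 ± 0.17, and Iigp1, with no count in arm II, at least 66.2-fold lower. Of 23 glycolysis genes 7 were lower (8 adjusted over the list alone), among them Pgk1 (-1.35 ± 0.15) and the lactate dehydrogenase gene Ldha (-1.15 ± 0.18). Of 25 effector genes 9 were lower and 1 was higher (10 and 4 adjusted over the list alone). Inhibitory receptor genes went up as a list, with 4 higher and 3 lower of 21 (6 and 3 adjusted over the list alone), such as Klrd1 (CD94), a receptor shared with NK cells, at 1.28 ± 0.21. Glucocorticoid targets were higher as a list, 10 higher and 5 lower of 33 (12 and 5 adjusted over the list alone), a call lost at adjusted p = 0.0726 with an estimated correlation. Its members include the transcription factor gene Cebpb (1.86 ± 0.21), Txnip, a regulator of glucose uptake (1.87 ± 0.26), and the chemokine receptor gene Cxcr4 (1.52 ± 0.23).

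Markers of keratinocytes, mononuclear phagocytes and neutrophils were lower in arm II as well, and those of fibroblasts were not called (1 higher and 0 lower of 18; camera adjusted p = 0.767). Of 31 keratinocyte genes 17 were lower in arm II (24 adjusted over the list alone), with Krt14 at 71.7 ± 10.3 CPM against 723 ± 168 (-3.33 ± 0.24), Krt5 at -3.04 ± 0.27, and Krt6b, a keratin of injured or inflamed epidermis with no count in arm II, at least 127-fold lower. Of 23 mononuclear phagocyte genes 7 were lower (12 adjusted over the list alone), including H2-Ab1, at 0.794 ± 1.12 CPM against 185 ± 7.49, and Cd74, which encodes the MHC class II invariant chain (-4.50 ± 0.52). Of 14 neutrophil genes 6 were lower (7 adjusted over the list alone), such as the alarmin gene S100a8 (-4.61 ± 0.95). The matrix protease gene Mmp3 had no count in arm II and was at least 169-fold lower. CD4 and Treg (3 lower, 1 higher), CD8 identity (4 lower), and chemokine and adhesion receptor genes (5 lower, 2 higher) were lower, and NK genes (2 higher) higher, only with the preset correlation. With an estimated correlation the adjusted p values were 0.0726, 0.238, 0.0726 and 0.0726. The NK list had a median above 0 and a mean below 0. Oxidative phosphorylation genes (8 of 49 lower, 18 lower and 1 higher adjusted over the list alone) were likewise called only that way (adjusted p = 0.282 with an estimated correlation).

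In GFP-positive TRM (2 libraries against 2) effector genes again lay lower in arm II. Ifng (ENSMUSG00000055170.4; chromosome 10, 118441046 to 118445892, plus strand, GRCm38) was at 1336 ± 49.1 CPM against 12557 ± 518 (log2 -3.23 ± 0.17, adjusted p = 2.48e-10) and Gzmb at 8923 ± 141 against 52872 ± 535 (-2.57 ± 0.14). Ccl3 (-2.49 ± 0.16), Il2 (-4.39 ± 0.41), Xcl1 (-1.45 ± 0.15), Tnf (-1.97 ± 0.30), the type 2 cytokine gene Il13 (-2.54 ± 0.39) and Il10 (-3.90 ± 0.45) were lower as well. Higher in arm II were Cxcr4 (2.54 ± 0.25), the RNA-binding protein gene Zfp36l2 (1.63 ± 0.17), Tsc22d3 (1.63 ± 0.24), Cebpb (1.73 ± 0.21) and Bbc3, which encodes the cell death protein PUMA (5.87 ± 0.80). In all 367 genes differed, 107 higher and 260 lower, a share of 29.2% higher that DESeq2 put at 41.2% (272 higher and 388 lower). The edgeR count was 179 without arm I GFP-positive A, 194 without arm I GFP-positive B and 222 without arm II GFP-positive B, and 626 without the low-count filter.

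Of 25 effector genes 12 were lower in arm II of the GFP-positive cells (15 lower and 3 higher adjusted over the list alone), of 35 TCR activation genes 7 (13 and 1), and of 35 interferon response genes 7, with 1 higher (12 and 1). Type 17 and type 2 genes (4 of 12), CD4 and Treg genes (3 of 10) and glycolysis genes (1 of 23, the hypoxia factor gene Hif1a at -1.52 ± 0.27) were lower. Of these, 5, 6 and 1 were lower when adjusted over the list alone. Beside these, keratinocyte genes were lower (14 of 31, 1 higher), with the suprabasal keratin gene Krt10 at -2.95 ± 0.26 and, in the other direction, Krt6b at 5.38 ± 0.95. Mononuclear phagocyte (4 of 23) and neutrophil genes (1 of 14) were lower too. The macrophage genes Retnla and Ccl24, with no count in arm II, were at least 119-fold and at least 89.3-fold lower. All these list calls held with an estimated correlation. Glucocorticoid targets were higher (7 higher, 2 lower of 33; 10 and 5 adjusted over the list alone), a call lost at adjusted p = 0.0542 with an estimated correlation. Calls of higher fibroblast (3 of 18) and mitochondrial genes (1 of 15) and of lower proliferation genes (7 of 39, 1 higher) were also lost. They had adjusted p = 0.357, 0.313 and 0.153 with an estimated correlation. Between the GFP-negative and GFP-positive comparisons of the arms, 50 genes were higher in arm II in both, where independent lists would share 2.12, 135 were lower in both, against 12.2, and 3 went in opposite directions, against 10.2. Over all genes the log2 differences correlated by 0.217.

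**Figure D1:**
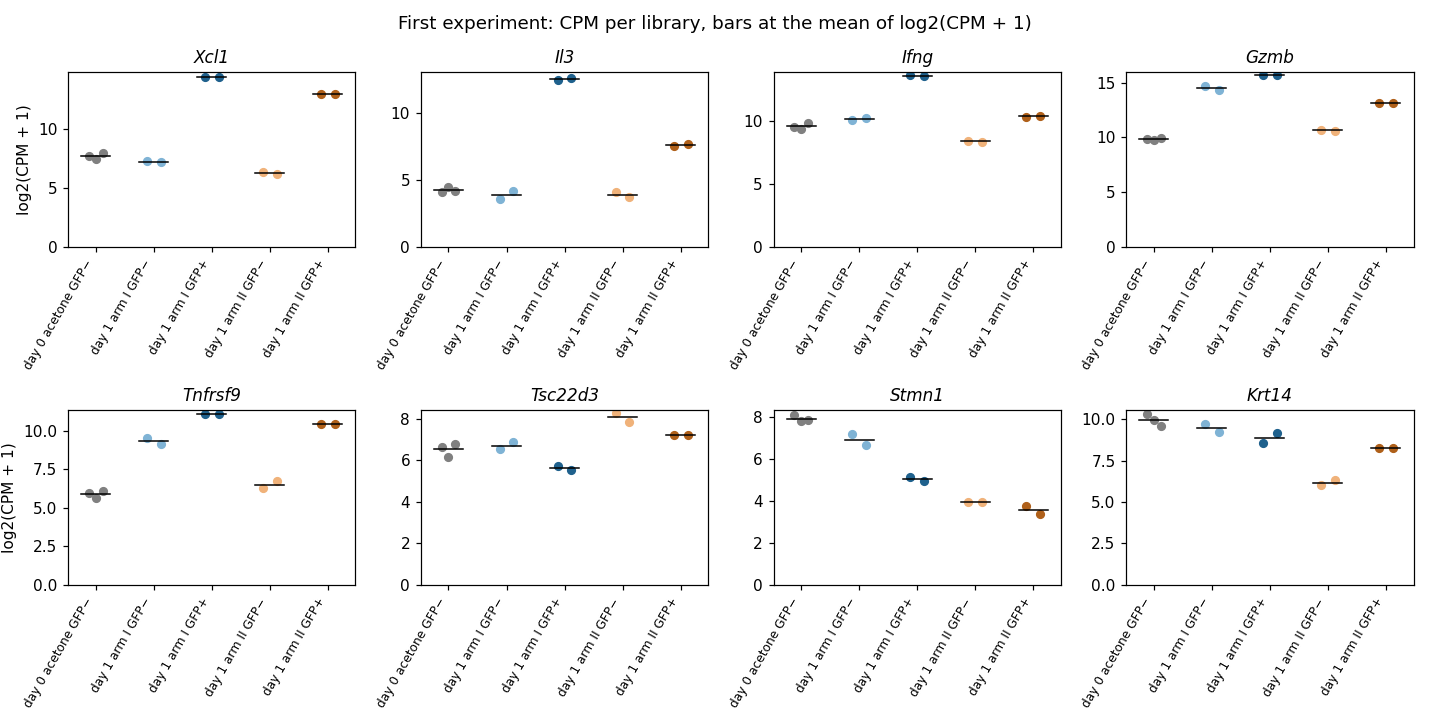
Expression of 8 genes in the day 0 acetone GFP-negative libraries and in the GFP-negative and GFP-positive libraries of arm I and arm II at day 1, as log2(CPM + 1). Each point is 1 library and each bar the mean of its group. Xcl1, Il3 and Ifng lie higher in GFP-positive than in GFP-negative libraries of both arms, and Gzmb lies higher in arm I (23532 ± 3309 CPM in GFP-negative cells) than in arm II (1589 ± 23.2 CPM).

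The comparison of day 1 with day 0 asked how GFP-negative TRM change in the 24 hours after retest. It sets the mean of both day 1 arms (4 libraries) against day 0 acetone (3 libraries), so it mixes TA and acetone. In these day 1 cells 18 of 39 proliferation and 17 of 31 keratinocyte genes were lower in arm II than in arm I. A mean fall in these lists was therefore unequal between the arms. Over the day 1 libraries Stmn1 ranged from 14.4 to 144.8 CPM against 227 to 274 at day 0. Top2a ranged from 0.794 to 42.0 CPM against 43.6 to 53.2. Proliferation genes fell: Stmn1 (ENSMUSG00000028832.11; chromosome 4, 134468320 to 134473843, plus strand, GRCm38) was at 68.8 ± 65.1 CPM against 245 ± 25.5 at day 0 (log2 -2.53 ± 0.16, adjusted p = 4.01e-09), with Tubb5 at -1.62 ± 0.13 and the mitotic gene Ube2c at -3.31 ± 0.32. The TCR complex gene Cd3g (-0.98 ± 0.11) and the chemokine receptor gene Cxcr6 (-0.65 ± 0.13) fell. Cxcr4 (1.98 ± 0.19), the metallothionein genes Mt1 (1.41 ± 0.15) and Mt2 (1.16 ± 0.14), Ptpn22 (1.31 ± 0.12), the inhibitory receptor gene Ctla4 (4.26 ± 0.64) and the protease inhibitor gene Serpina3g (3.35 ± 0.31) rose. Cxcr4 and Ptpn22 were also higher in arm II than in arm I in these day 1 cells, so their mean rise was unequal between the arms. Cxcr4 ranged from 69.4 to 214 CPM at day 1 against 25.2 to 37.0 at day 0. The change from day 0 was not tested in each arm alone. In all 814 genes changed, 361 higher and 453 lower at day 1. The count was 529 without day 0 acetone C and 511 without arm I GFP-negative B. It was 466 with the replicate block and 1259 with DESeq2.

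Of 39 proliferation genes 22 fell (28 adjusted over the list alone), which held with an estimated correlation. The other list calls were lost that way. Glucocorticoid targets were higher (10 higher and 4 lower of 33; 15 and 4 adjusted over the list alone; adjusted p = 0.082 with an estimated correlation), as were inhibitory receptors (7 higher and 2 lower of 21; adjusted p = 0.0888 with an estimated correlation). Both lists also lay higher in arm II than in arm I in these day 1 cells, by camera with the preset correlation (10 higher and 5 lower, and 4 higher and 3 lower). Day 0 here was acetone only, and the day 1 mean includes TA. For these lists an effect of TA therefore cannot be separated from one of the day. CD8 identity genes (6 of 17 lower, 1 higher; adjusted p = 0.151 with an estimated correlation) and chemokine and adhesion receptors (7 of 21 lower, 1 higher; adjusted p = 0.0888 with an estimated correlation) were lower. Beside them, 14 of 31 keratinocyte genes were lower and 4 higher (adjusted p = 0.0888 with an estimated correlation): the basal keratin genes Krt14 (-2.15 ± 0.17), Krt5 (-2.43 ± 0.19) and Krt15 (-3.20 ± 0.32) fell, and Krt6a, a keratin of activated epidermis, rose by 4.23 ± 0.49. Krt14 libraries overlapped, at 64.3 to 842 CPM at day 1 against 763 to 1290 at day 0. Of 18 fibroblast genes 7 were lower, such as the proteoglycan gene Dcn (-5.25 ± 0.90; adjusted p = 0.0888 with an estimated correlation), and 3 of 14 neutrophil genes were higher (adjusted p = 0.082 with an estimated correlation).

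For day 0 TA and for both day 6 groups, 3 sets of 2 GFP-negative libraries (K, L and M) carry headers that do not tell these groups apart here, so only the possible results can be given. Day 0 acetone differed from the 3 sets in 104, 409 and 528 genes, and 1 of these is the effect of TA at day 0. The sets differed from each other in 230, 662 and 1029 genes, 1 of which is the effect of TA at day 6. Over the 6 libraries Gzmb ranged from 247 to 2418 CPM (median 1399), against 848 to 975 CPM (median 907) in the 3 libraries of day 0 acetone. Tsc22d3 ranged from 104 to 369 CPM (median 162), against 71.0 to 109 CPM (median 98.4). The count of 104 became 68, 49 and 39 without day 0 acetone C, set L replicate A and set L replicate B, and that of 528 became 344 without day 0 acetone C. The count of 230 became 90, 64, 86 and 112 without set L replicates A and B and set M replicates A and B, and that of 1029 became 621, 596 and 584 without set K replicate A and set M replicates A and B.

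In the second experiment, CD69+CD103+ cells at day 11 and day 42 (8 libraries, acetone and TA together) were set against CD69+CD103+ cells at day 2 (2 libraries), to ask how these cells change as they settle in the skin. Day 2 cells were untreated, while all later cells had acetone or TA as treatment. Day and treatment therefore cannot be told apart in this comparison. Genes of recirculation fell: S1pr1 (ENSMUSG00000045092.8; chromosome 3, 115710433 to 115715072, minus strand, GRCm38), which guides T cells out of tissue, was at 6.93 ± 6.28 CPM against 103 ± 16.6 at day 2 (log2 -4.60 ± 0.28, adjusted p = 1.03e-08), with the lymph node homing receptor gene Ccr7 at -3.69 ± 0.21 and the transcription factor gene Lef1 at -3.81 ± 0.53. TRM genes rose, among them Cdh1, which encodes E-cadherin (2.53 ± 0.20), Litaf (2.13 ± 0.17) and the signalling regulator Rgs1 (1.67 ± 0.14). The heat shock gene Hspa1b was at 4683 ± 1638 CPM against 1229.7 ± 114 (1.86 ± 0.12). Lower were Tnfrsf4 at -3.83 ± 0.24, Ctla4 at -2.51 ± 0.20, Il17a at -3.55 ± 0.41 and Il13 at -2.90 ± 0.34, while TCR activation genes were not called as a list (6 higher and 9 lower of 34; camera adjusted p = 0.372), nor were effector genes (6 higher and 4 lower of 27; 0.664). Of 12236 genes 1005 changed, 407 higher and 598 lower, a share of 40.5% higher that DESeq2 put at 52.6% (698 higher and 630 lower). The edgeR count was 436 without day 2 CD69+CD103+ replicate 1 and 401 without replicate 2.

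By list, 11 of 27 TRM core genes rose and 2 fell (13 and 3 adjusted over the list alone), and 10 of 29 recirculation genes fell and 1 rose (14 and 2). Interferon response genes (18 of 38, 25 adjusted over the list alone) fell, such as Ifi27l2a (-4.44 ± 0.28) and Gbp2 (-3.38 ± 0.25). Glycolysis genes (8 of 24) fell, with Ldha at -1.49 ± 0.11 and the pyruvate kinase gene Pkm at -1.59 ± 0.16, as did 8 of 40 proliferation genes. Glucocorticoid targets rose (19 higher and 5 lower of 33), including Rgs2 (2.50 ± 0.17), the phosphatase gene Dusp1 (2.22 ± 0.18) and the clock gene Per1 (2.37 ± 0.33). Dissociation and heat shock genes rose (23 of 33, 27 adjusted over the list alone), with the immediate-early genes Fosb (2.77 ± 0.17) and Fos (1.97 ± 0.16). Some of these genes, such as Dusp1 and Per1, also answer to handling of cells. The later libraries include cells given TA, a glucocorticosteroid, and the day 2 cells had none. For glucocorticoid targets an effect of TA therefore cannot be separated from one of the day. The list calls given so far for this comparison held with an estimated correlation, as did that of lower neutrophil genes (6 of 11), of which S100a8 had no count in the 8 later libraries and was at least 971-fold lower. Keratinocyte genes were lower (10 of 32, 1 higher; adjusted p = 0.107 with an estimated correlation), led by Krt6a (-6.44 ± 0.28).

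The list calls of this comparison lost with an estimated correlation were lower oxidative phosphorylation (18 of 49; adjusted p = 0.0674), type 17 and type 2 (5 lower and 2 higher of 19; 0.0858), CD4 and Treg (4 lower and 1 higher of 12; 0.0858) and NK genes (5 lower and 1 higher of 13; 0.0549), and higher endothelial and melanocyte genes (0 of 16; 0.0674). Foxp3, the regulatory T cell factor gene, was at 0.0394 ± 0.111 CPM against 20.8 ± 10.7 at day 2 (-9.39 ± 1.10). The 4 day 11 and day 42 groups carry headers that do not tell day and treatment apart here. Set against each other 2 and 2, in the 3 possible ways, they differed in 49, 58 and 204 genes. Among these 3 are the effect of TA and that of the day. The highest count, 204, was 129, 126 and 120 without replicate 2 of set P, replicate 1 of set R and replicate 1 of set S, and the lowest, 49, was 28 without replicate 1 of set S.

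At day 2 the comparison of CD69+CD103+ cells (2 libraries) with the mean of the other 3 subsets (6 libraries) asked what already marks cells with the TRM surface phenotype. The chemokine gene Ccl1 (ENSMUSG00000020702.13; chromosome 11, 82176657 to 82305690, minus strand, GRCm38) was at 134 ± 3.13 CPM against 27.9 ± 35.6 (log2 3.47 ± 0.26, adjusted p = 1.08e-06). Xcl1 was higher by 1.79 ± 0.24, Il13 by 3.22 ± 0.35, Il3 by 6.64 ± 0.80, Gzmc by 2.05 ± 0.23 and the skin-homing receptor gene Ccr8 by 1.72 ± 0.24. The inflammatory chemokine gene Ccl5 was lower (-1.94 ± 0.18), at 249.6 ± 42.6 CPM against 1051 ± 509. Itgae, which encodes CD103 and was sorted on, was higher by 2.77 ± 0.28. Cd69 transcripts overlapped, at 370 to 528 CPM against 330 to 524 in the other subsets, although CD69 was sorted on too. The mean covers 3 unlike subsets, and some of their libraries came close to CD69+CD103+ cells. Xcl1 reached 444 CPM in them against 447 to 481, and Itgae 92.5 against 70.7 to 88.7. S1pr1 went down to 81.8 CPM against 90.9 to 114. These 3 genes thus do not mark CD69+CD103+ cells alone. Of the other 3 subsets, 1 was sorted as CD69-CD103+, so for Itgae such an overlap can come from the sort itself. Il3 (up to 11.0 against 43.0 to 78.7) and Ccr8 (up to 17.5 against 22.8 to 25.2) did not overlap. In all 45 genes differed, 39 higher and 6 lower, a share of 86.7% higher that DESeq2 put at 68.9% (73 higher and 33 lower). The edgeR count was 74 without subset U replicate 1, 18 and 20 without CD69+CD103+ replicates 1 and 2, and 29 without subset W replicate 2, and it was 173 without the low-count filter.

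Of 27 TRM core genes 3 were higher (5 adjusted over the list alone), and recirculation genes were lower as a list with 0 of 29 passing (2 adjusted over the list alone), S1pr1 at -1.37 ± 0.33 (adjusted p = 0.111, but 5.82e-05 without the low-count filter and 0.000346 with DESeq2). Type 17 and type 2 genes (2 of 19), NK genes (2 of 13) and CD4 and Treg genes (1 of 12) were higher. With no member passing, proliferation genes (0 of 40) were higher and interferon response (0 of 38) and endothelial and melanocyte genes (0 of 16) lower by the list test. Beside these, mononuclear phagocyte (4 of 26; 8 adjusted over the list alone), neutrophil (2 of 11; 6) and keratinocyte genes (2 of 32; 11) were higher in CD69+CD103+ cells. All calls so far held with an estimated correlation. Lost that way were higher effector (4 higher and 1 lower of 27; adjusted p = 0.174 with an estimated correlation), TCR activation (1 higher and 1 lower of 34; 0.0539), fibroblast (1 of 21; 0.0903), gamma-delta T cell (1 of 7; 0.0964), glycolysis (0 of 24; 0.0849) and mitochondrial genes (0 of 15; 0.248). Which header holds which of the other 3 subsets was not used here. Set 2 against 2 in the 3 possible ways, the day 2 subsets differed in 4, 37 and 203 genes. The count of 4 became 24 without subset U replicate 2 and 11 and 7 without subset V replicates 1 and 2, and that of 203 became 89 and 117 without CD69+CD103+ replicates 1 and 2, 115 without subset V replicate 2 and 113 without subset W replicate 2. Lists were not tested in the contrasts with or among sets K, L and M, nor in those of 2 sets or subsets against 2. In the comparisons with list tests, survival and apoptosis genes and mast cell and basophil genes were never called. Among these comparisons lipid uptake and oxidation genes were called only within arm I (lower in GFP-positive cells, 1 of 21; adjusted p = 0.146 with an estimated correlation).

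**Figure D2:**
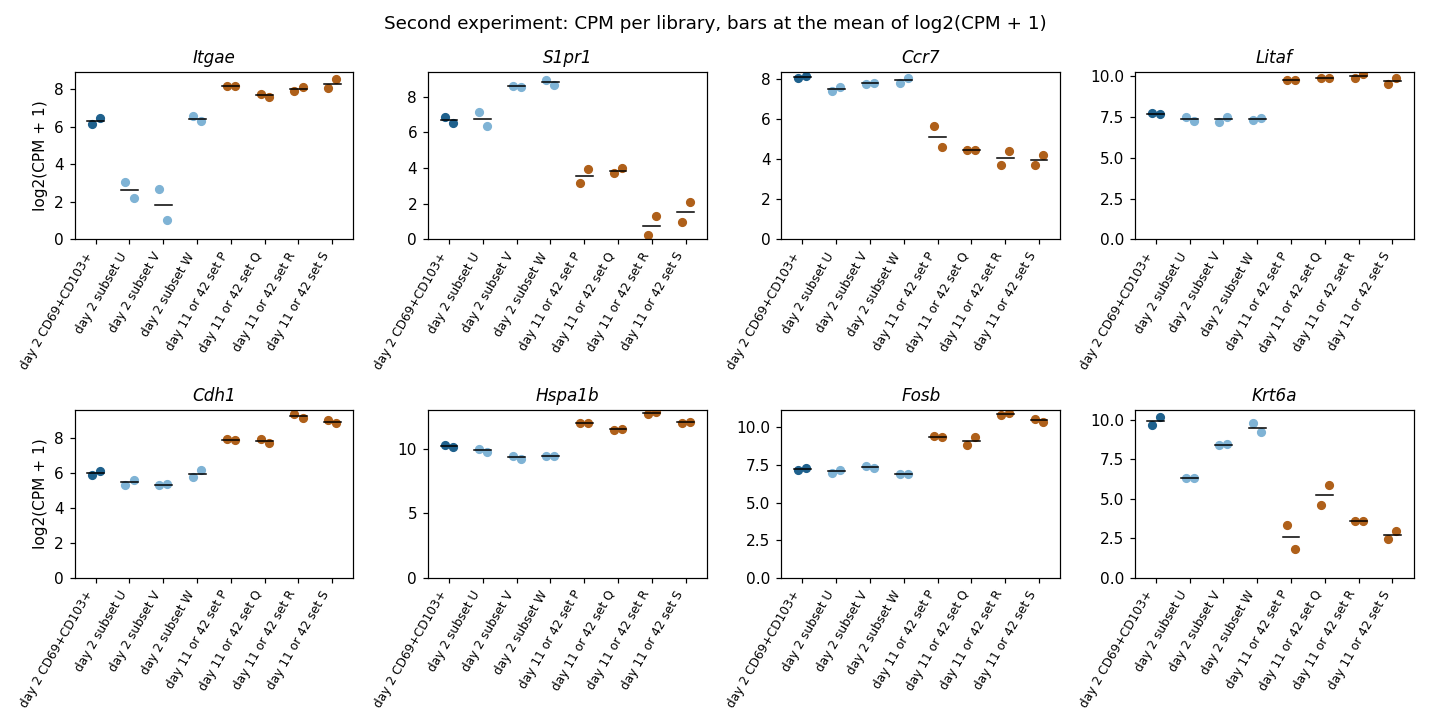
Expression of 8 genes in the libraries of the second experiment, as log2(CPM + 1): day 2 CD69+CD103+ cells, the other day 2 subsets U, V and W, and the day 11 and day 42 CD69+CD103+ sets P, Q, R and S; each point is 1 library and each bar the mean of its group. S1pr1 and Ccr7 lie lower and Litaf and Hspa1b higher in the 8 day 11 and day 42 libraries than in day 2 CD69+CD103+ cells (Litaf 921 ± 111 against 209.6 ± 10.2 CPM).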

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

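The tests of keratin spread, of genes left out and of equal totals in this part were chosen only after the results were seen. The following results were picked out because the GFP difference at day 1 differed between the arms by a test of the interaction, with log2 values of arm II minus arm I from edgeR with Benjamini-Hochberg adjustment. The difference was smaller in arm II for Il3, at -4.96 (8.75 ± 0.28 in arm I, 3.79 ± 0.25 in arm II; adjusted p = 7.26e-08), Ccl3 -2.60 (5.66 ± 0.18 and 3.06 ± 0.16; 1.07e-06) and Ifng -1.44 (3.44 ± 0.17 and 2.00 ± 0.16; 0.00146). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, had a larger one, 2.23 (1.73 ± 0.20 and 3.95 ± 0.22; 0.00032), as did the glycolysis gene Pgk1, 0.95 (0.36 ± 0.15 and 1.31 ± 0.15; 0.0357). Over both arms Tnfrsf9 ranged from 1387 to 2132 CPM in GFP-positive and from 75.1 to 723 CPM in GFP-negative libraries. Its arm difference thus lay mostly in GFP-negative cells. Pgk1, like Stmn1 below, was lower in arm II in GFP-negative cells, so a larger value need not mean more transcript in GFP-positive cells. Stmn1 differed by 1.55 (-1.93 ± 0.20 and -0.39 ± 0.25; 0.0215), a call lost without arm I GFP-negative A (0.136), GFP-positive A (0.0505) or GFP-positive B (0.0943) and without arm II GFP-negative A (0.0571), GFP-negative B (0.0541) or GFP-positive A (0.135). Strada, a partner of the kinase LKB1, differed by -6.92 (-0.60 ± 0.57 and -7.52 ± 1.03; 0.00817), a call lost without arm II GFP-positive B (0.0561). External control transcripts, which no comparison uses, had 16 reads in set M replicate A.

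Keratinocyte transcripts were lower in arm II in GFP-negative cells, alongside the T cell groups of effector and interferon genes. If carried-over keratinocyte RNA of the same make-up differed only in amount between the arms, the keratin genes would share 1 log2 value. Over 8 keratin genes they did not, with a Cochran's Q per degree of freedom of 30.1, from Krt16 at -7.82 ± 0.85 to Krt10 at -0.52 ± 0.23. With the keratinocyte genes left out, 749 of 775 called genes kept call and direction, so most calls do not depend on these genes being present. TMM scaling allows for reads taken up by a few genes with or without this step. The step therefore cannot decide whether keratinocyte reads took room from other genes. A treatment that changes the epidermis as well as its T cells could give this pattern, but no test here separates that from carry-over of epidermis in a different state.

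Genes called between the arms in GFP-negative cells were mostly lower in arm II (545 of 775), which also had fewer reads and a larger mitochondrial share. At equal totals 707 of 775 kept call and direction, so the number of reads does not account for most calls. Without mitochondrial transcripts 770 did, but this scaling leaves calls nearly unchanged by that step in every comparison, so it does not test the mitochondrial share as a sign of cell or RNA quality. A treatment effect or a difference in cell quality, sorting or handling between the arms could each give the pattern, and these were not told apart.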

How the results depend on the processing

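No called value of a named gene changed sign. The balance of calls turned in 3 comparisons: from 648 higher and 754 lower to 741 and 716 with keratinocyte genes left out (GFP, both arms), from 470 and 465 to 593 and 613 without the low-count filter (GFP, arm II), and from 407 and 598 to 698 and 630 with DESeq2 (day 11 and 42 against day 2). Size factors by median of ratios moved no count of called genes by over 1.5 times, nor did leaving out mitochondrial transcripts or keratinocyte genes or thinning to equal totals, which were chosen after seeing the data. Of 594 named-gene results, the alternatives with all libraries gave 3847 values with the same call, 49 weaker and 63 stronger, and leaving out a library 3267, 453 and 13. Without the low-count filter, which tests more genes, counts became 310 (interaction of arm and GFP), 626 (arms, GFP-positive), 173 (CD69+CD103+ against other day 2 subsets), 297 (day 0 acetone against sets, lowest), 389 (pairs of sets, lowest), 238 and 537 (day 11 and 42, lowest and highest), and 81 and 422 (day 2 subsets). With DESeq2 they became 978 (GFP, arm I), 1460 (arm II), 299 (interaction), 1273 and 660 (arms, GFP-negative and GFP-positive), 1259 (day 1 against day 0), 267 and 909 (day 0 acetone against sets), 504 (pairs of sets, lowest), 106 (CD69+CD103+), 239 and 519 (day 11 and 42), and 34 and 441 (day 2 subsets). With an estimated correlation 55 of 102 list calls remained. For the filter and DESeq2 the cause was not tested beyond this.

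Whether a letter marks the same source in different groups is not given. Differences of A and B correlated between groups by -0.190 to 0.106 over 28 pairs. No pairing was detected, but such correlations cannot exclude one. The replicate block gave 466 (day 1 against day 0), and 67 and 304 (day 0 acetone against sets, lowest and highest), moved no other count by over 1.5 times, and kept all 71 list calls of the first experiment while adding 3: mononuclear phagocyte genes higher in GFP-positive cells over both arms (adjusted p = 0.0367) and in arm II (0.0348), and interferon response genes in the interaction (0.0315).

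Leave-one-out ranges, in which a lone library is assumed to vary like the other groups, were 312 to 412 (GFP, arm I), 47 to 104 (interaction), 356 to 556 and 179 to 251 (arms, GFP-negative and GFP-positive), 511 to 739 (day 1 against day 0), 39 to 113 and 344 to 532 (day 0 acetone against sets), 64 to 255 and 584 to 980 (pairs of sets), 401 to 1041 (day 11 and 42 against day 2), 18 to 74 (CD69+CD103+), 28 to 70 and 120 to 213 (day 11 and 42), and 3 to 24 and 89 to 251 (day 2 subsets). They were 1037 to 1385 for the GFP comparison over both arms and 626 to 741 for arm II.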

Other observations

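The test of heat shock levels and of equal totals in this part was chosen only after the result was seen, and the tests over splits were written before. Over the 6 libraries of sets K, L and M, Ifng ranged from 249 to 786 CPM (median 514), Ccl3 from 221 to 378 CPM (median 323) and Xcl1 from 72.0 to 384 CPM (median 280.5). In the 6 libraries of day 2 subsets U, V and W, Ccr7 ranged from 168 to 269.7 CPM (median 219) and S1pr1 from 81.8 to 493 CPM (median 383), and Gzmb, whose product kills target cells, from 6944 to 22799 CPM (median 10940.3).

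Heat shock and immediate-early genes were higher at day 11 and day 42 than at day 2. Over the dissociation and heat shock list the lowest of 8 later libraries lay 0.719 log2 CPM above the highest of 8 day 2 libraries, as stress during handling that differed between the days would give. A lasting state of settled TRM, or the acetone or TA that only the later groups received, could give the same. The test cannot tell these apart. Deeper sequencing of the day 2 CD69+CD103+ libraries does not account for the calls, since 869 of 1005 genes kept call and direction at equal totals.

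Each split of the same libraries was refitted as 2 groups, without a mean per sorted group, so it does not test the main counts of 1402, 814, 204 and 203. The main fits took only the spread within sorted groups. A split also takes differences between arms, GFP states or sets as spread, and one that mixes them tends to call few genes. The other splits are therefore no baseline for the main counts. Of 35 splits of the day 1 libraries, 1 called as many genes as the real one, which is included: GFP gave 338, the split by arm 137, and no other more than 1. For day 1 GFP-negative against day 0 acetone 1 of 35 splits reached the 25 genes of the real one, and no other called more than 2. For the day 11 and day 42 sets the highest of the 3 possible splits called 52 genes and no split outside these 3 more than 1, and for the day 2 subsets 157 and 2; in both 1 of 35 splits reached the highest, but a choice among 3 cannot give a share under 0.05.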
